A study of Mus musculus with 8 samples.

How the data were processed

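Lung cells of young and old mice, uninjured or taken 7 days after bleomycin, were profiled by single-cell RNA sequencing in 8 libraries, 2 in each of 4 groups. Per the labels' protocols, CD45-positive immune cells and negatively selected fibroblasts were captured in droplets made by templated emulsification (PIPseq), and libraries were sequenced as paired ends on a NovaSeq instrument. The deposited values are counts of transcripts per gene and barcode, whole numbers with 1 matrix per library, and the genome build was mm10 per the submitters' processing notes. The aligner, the counting program, the annotation and the rule by which barcodes were called cells are not given in the sources used here. Each file lists the same 32227 genes, which were named by the symbols in the files. Ages are not given in the sources used here.

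Barcodes were kept with at least 500 counts, at least 200 genes and at most 20% mitochondrial counts, which removed 2 of 8196. Doublets were called per library with a custom version of Scrublet's approach (simulated doublets and nearest-neighbour scores), not the published program, with an expected share of 5%. It marked 0.305% of the cells, too few for the call to have worked, so doublets are in effect still present. After removing the marked cells 8169 remained. Counts per cell were scaled to 10000 and log-transformed, and cells of all libraries were clustered together without batch correction, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and scikit-image 0.26.0 were used.

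A cluster was named after the class whose fixed markers scored highest, among 18 marker lists, if at least 3 of them were detected and its 10 leading genes by fold did not hold more markers of another class. That last rule was adjusted after the clusters were seen. A strict tally left clusters without a name over single genes (Arg1, Des and Cd209a are also on another class's list), so at least 2 leading genes of another class that names a cluster were then required. Under the strict tally cluster 5, with 1 leading gene of another class and none of its own, would have had no name. The monocyte/macrophage class was therefore also tested without it, an alternative chosen after seeing the data. Cluster 21, 122 barcodes of old injured library 2, kept no name and is in no class. Classes are "like" the cell type they are named after, and all differences rest on these rebuilt names.

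Counts were summed per library over the cells of a class, with a library left out where it had under 20 such cells. The sums were tested with edgeR 4.0.16 (limma 3.58.1, statmod 1.5.0, R 4.3.3) by the quasi-likelihood test with robust dispersion, TMM scaling, the filterByExpr filter and 1 mean per group, in a fit over all libraries. Contrasts were injury as the mean of both ages, old against young in uninjured lungs, old against young in injured lungs, and the injury by age interaction. P-values were adjusted by the Benjamini-Hochberg method over the genes of a class and contrast, and genes under an adjusted p of 0.05 count as changed. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Between the 2 libraries of a group, log CPM sums correlated across genes with r from 0.799 to 0.966. Genes are not independent replicates, so these values only describe how alike the libraries are.

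The genes named for injury are the 12 with the largest rise and the 12 with the largest fall among changed genes with the same sign at both ages and a mean log2 CPM of at least 5. For each other contrast they are the 5 largest rises and 5 largest falls. Gene models without a proper symbol, mitochondrial, ribosomal and immune receptor genes, and genes over 5 times higher in another class were skipped. A fixed set of fibrosis, cytokine and arginine and proline genes was added whatever its result, and list members are quoted as examples, those with the smallest p first. A few genes that these rules name are left unprinted, and the counts include them. Further names outside these rules, such as Eln, Clec4n, Apoe and Lif with age, Col11a1, and the interaction values of Col1a1 and Eln, were chosen after their values were seen. Gene lists, 12 for every class, 9 more for fibroblasts and 9 more for both macrophage classes, and the markers of the other classes were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists of a class and contrast. Lists with under 5 measured members were not tested. Shares of immune cells were compared by a two-sided exact permutation test of mean shares, for classes with at least 1% of immune cells, adjusted over the classes.

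These groups, tests, lists, naming rules for genes and alternatives were fixed before the data were examined. The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, a stricter cell filter, every deposited barcode, doublets kept, clustering at resolution 0.5 and 2, genes higher in another class removed, and each library left out in turn. Chosen after seeing the data were the removal of the 5% of cells with the highest doublet scores, no minimum number of cells, the class without cluster 5, and tests of dendritic cells, of injured fibroblast cluster 8 and of all cells outside the 3 tested classes. The last differ in class mix between groups. Their ratio of log2 changes is a median over called genes with at least 20% of the class's CPM there.

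The gene tests were run on simulated counts with 200 genes changed by 2- or 4-fold in injured libraries. In fibroblasts 63.9% of the 2-fold and 91.6% of the 4-fold changes were recovered among 12362 genes, with 168 calls of which 19 were of unchanged genes. With changes in the old injured group alone, 22 of 122 calls for age in injured monocyte/macrophages were of unchanged genes. With the same change in injured libraries of both ages, 10 genes were called there, and with no change simulated 10 genes were called for age in uninjured fibroblasts. In alveolar macrophages 38.0% and 83.7% were recovered among 8408 genes, and in monocyte/macrophages 24.5% and 62.2% among 12652 genes. With 4-fold changes in the old injured group alone, the interaction test recovered 45.9%, 22.7% and 15.0% in the 3 classes, so the counts for interactions miss many differences of that size.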

Results

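Single-cell transcripts were counted in lungs of young and old wild-type mice, either uninjured or injured with bleomycin, a DNA-damaging drug that causes lung inflammation followed by scarring. Injured lungs were taken 7 days after 3 U per kg of bleomycin was given through the airway. Each of the 4 groups has 2 libraries, and each library mixes immune cells captured by the surface protein CD45 with fibroblasts left after epithelial, endothelial, immune, mural and red blood cells were removed. The title of the series asks how inflammatory signals between cell types set up an exchange of metabolites that favours fibrosis, so fibroblasts and macrophages are described first. The deposited files hold 8196 barcodes. Total counts were 5406220 and 2746527 in young uninjured, 7961633 and 5408205 in young injured, 4325022 and 3632217 in old uninjured, and 10433654 and 3428364 in old injured libraries 1 and 2. The median count per cell ran from 2362.5 in old injured library 2 to 8824 in old injured library 1.

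Clustering gave 22 clusters, of which 21 were named from marker genes. Fibroblast-like cells, which make collagen and other matrix, formed clusters 0, 1, 2 and 8. Alveolar macrophage-like cells, the resident phagocytes of the air spaces, formed clusters 6, 15 and 19, and other monocyte/macrophage-like cells formed clusters 3, 5, 11, 12, 13 and 17. Dendritic cell-like, T cell-like, B cell-like, neutrophil-like, plasma cell-like and endothelial-like cells made up the rest. Cluster 10, the endothelial-like one, also had the epithelial markers Sftpc and Scgb1a1 among its leading genes. Summed counts per library ran from 642155 to 3777824 in fibroblasts, from 190279 to 1765502 in alveolar macrophages and from 176559 to 6063080 in monocyte/macrophages. Young uninjured library 2 had 17 monocyte/macrophages and was left out of that class, so that group is 1 library there. Nothing in the labels says that the 2 libraries of a group came from different animals, so p-values measure only the spread between these samples, which may be technical. Changes below are log2 fold changes ± SE from edgeR's quasi-likelihood test, and levels are counts scaled to a common total (CPM) as mean ± SD over the 2 libraries of a group.

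In fibroblasts, the comparison of injured with uninjured lungs asks what bleomycin changed at both ages. Fibrillar collagen and matrix genes rose, among them Col3a1 by 2.48 ± 0.15, Col1a1 by 2.08 ± 0.14, Sparc, a collagen-binding matrix protein, by 2.01 ± 0.14 and Fn1, which encodes fibronectin, by 2.71 ± 0.17 (edgeR adjusted p = 6.6e-09, 2.5e-08, 4.5e-08 and 5.4e-08). Col1a1 stood at 2578 ± 264 CPM in young uninjured and 7234 ± 1658 in young injured fibroblasts, and at 759 ± 93.3 and 4826 ± 508 in old ones. Acta2, the actin of contractile myofibroblasts, rose by 3.51 ± 0.50 and Tnc, the matrix protein tenascin C, by 4.46 ± 0.77 (adjusted p = 0.0067 and 0.015). Acute phase and inflammatory genes rose with them: Lcn2, which binds bacterial iron carriers, by 4.41 ± 0.35, Saa3, a serum amyloid A protein, by 4.10 ± 0.79 and Serpina3n, a protease inhibitor, by 2.91 ± 0.16. Inmt, a methyltransferase abundant in alveolar fibroblasts, fell by 2.21 ± 0.16 (edgeR adjusted p = 4.5e-08), from 9776 ± 442 to 2118 ± 80.4 CPM in young lungs.

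Of 12950 genes tested in fibroblasts, 2373 rose and 2290 fell with injury, and in the cells outside the 3 tested classes the called genes had a median of 0.741 times this change. The other top named rises were Spp1 (6.83 ± 0.31), osteopontin, Cxcl13 (4.61 ± 0.68), a B cell chemokine, Fst (4.17 ± 0.20), an activin inhibitor, Chl1, Nrep, Ccn4 and Hp. Spp1 rose in macrophages too, and carry-over of their RNA was not tested. The other top falls were Kcnc1, with 2 counts in all young injured fibroblasts, Zfp185, Nrg2, Ppl, Iho1, Kcna2, Gria1, Igfbp3, Nup210l, Thsd7b and Sox6. Cthrc1, a marker of fibrosis-associated fibroblasts, had 3 counts in old uninjured fibroblasts, and its level was 65.8 ± 66.1 CPM in young injured and 62.5 ± 46.1 in old injured ones (adjusted p = 0.032 by edgeR). Postn, a matrix protein, rose by 2.38 ± 0.45 and Timp1, an inhibitor of matrix proteases, by 2.61 ± 0.31 (adjusted p = 0.0053 and 0.00097). Il6, an inflammatory cytokine, did not pass the test at 0.03 ± 0.14, and its relative Lif did not at 0.27 ± 0.19 (adjusted p = 0.87 and 0.27).

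Of the 28 measured collagen and matrix genes, 22 rose and 1 fell with injury, with the same counts adjusted over the list alone (camera adjusted p = 1.6e-21; adjusted p = 0.094 with an estimated correlation). Col11a1, at -1.26, was the 1 that fell. Of the 15 fibrotic fibroblast genes 12 rose, with 12 adjusted over the list alone, led by Sfrp1, a secreted Wnt inhibitor, at 2.58 ± 0.14 (camera adjusted p = 3.1e-14; adjusted p = 0.094 with an estimated correlation). Of the 29 inflammatory fibroblast genes 18 rose and 2 fell, or 19 and 2 adjusted over the list alone, including the chemokines Cxcl12 (1.59 ± 0.12) and Ccl8 (2.55 ± 0.27) (camera adjusted p = 2.4e-11; adjusted p = 0.094 with an estimated correlation). Enzymes that process and crosslink collagen followed, with 18 of 27 rising and 1 falling, or 20 and 2 adjusted over the list alone, such as the lysyl oxidase Lox (1.48 ± 0.12) and the prolyl hydroxylase P4ha3 (2.69 ± 0.26) (camera adjusted p = 7.5e-07; adjusted p = 0.13 with an estimated correlation). Contractile genes rose in 12 of 19 cases, or 13 adjusted over the list alone, such as Tpm2 (1.87 ± 0.17) (camera adjusted p = 2e-07; adjusted p = 0.23 with an estimated correlation).

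Cell cycle genes rose in 32 of 39 cases in injured fibroblasts, also 32 adjusted over the list alone, among them Birc5 (3.01 ± 0.34) and Pclaf (3.63 ± 0.42) (camera adjusted p = 1.6e-14; adjusted p = 0.20 with an estimated correlation). Genes of oxidative phosphorylation rose in 21 of 26 cases, or 22 adjusted over the list alone, such as Cox6c, a subunit of cytochrome c oxidase, by 2.16 ± 0.14 (camera adjusted p = 2.6e-15; adjusted p = 0.20 with an estimated correlation). The same list also rose in 21 of 26 cases in the cells outside the 3 tested classes, a comparison added after seeing the data. Immediate early and heat shock genes went the other way, with 17 of 26 falling and 1 rising, or 18 and 2 adjusted over the list alone, such as Klf2 at -1.40 ± 0.13 and Fos at -1.17 ± 0.15 (camera adjusted p = 1.7e-07; adjusted p = 0.35 with an estimated correlation). Of the 22 alveolar fibroblast identity genes 10 fell and 4 rose, the same as adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.52 with an estimated correlation). Among the 21 measured genes of arginine, ornithine and proline metabolism, 7 rose and 3 fell, also adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.37). Aldh18a1, which makes the proline precursor, rose by 0.58 ± 0.18, and the arginine transporter Slc7a2, whose level is over 5 times higher in alveolar macrophages, by 1.56 ± 0.23 (edgeR adjusted p = 0.019 and 6.5e-05). Pycr1, the last step of proline synthesis, Oat, which links ornithine to proline, and the transporter Slc7a1 stood at -0.14 ± 0.28, 0.14 ± 0.14 and -0.27 ± 0.24 (adjusted p = 0.73, 0.46 and 0.40). Monocyte/macrophage markers moved in the fibroblast sums as well, with 8 of 16 rising and 1 falling, also adjusted over the list alone (camera adjusted p = 0.0008; adjusted p = 0.34 with an estimated correlation). Different clusters held most fibroblasts, clusters 0 and 1 in young uninjured, 1 and 2 in old uninjured and 8 in both injured groups. Without old uninjured library 2, 2975 genes passed instead of 4663.

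**Figure D1:**
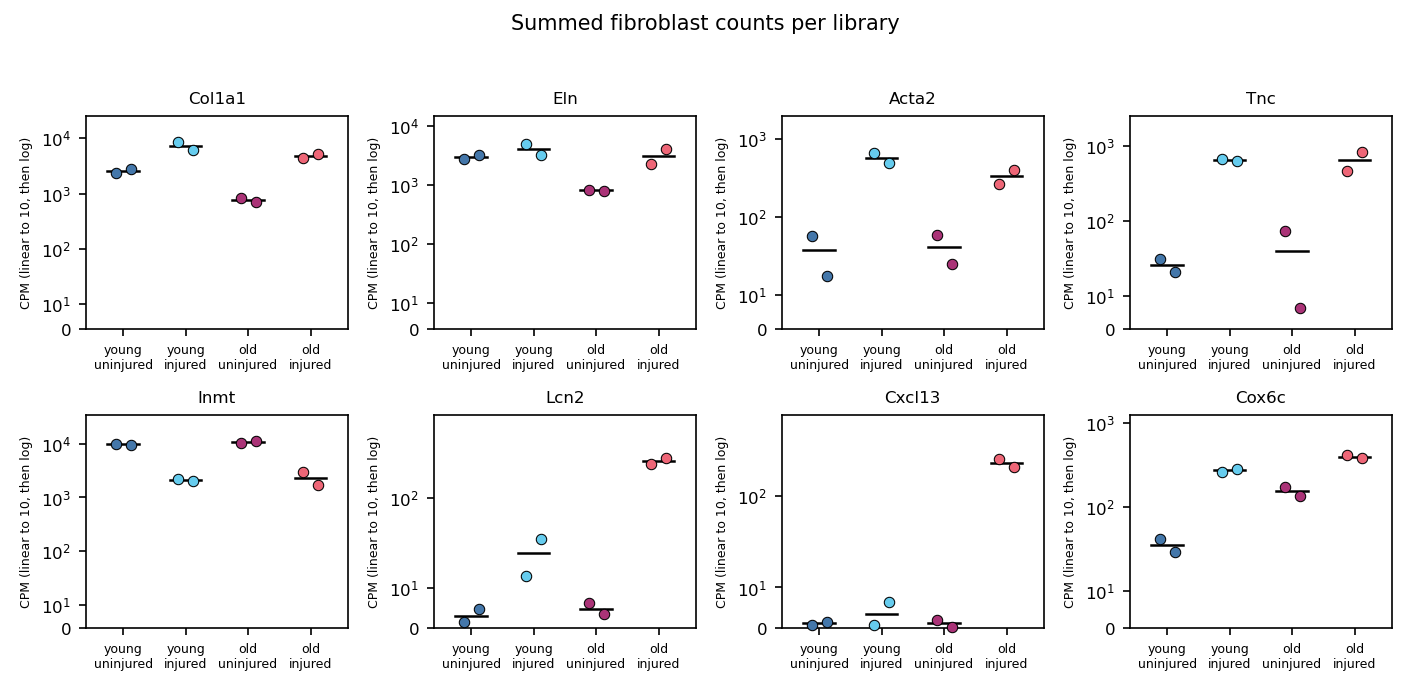
Levels in CPM of Col1a1, Eln, Acta2, Tnc, Inmt, Lcn2, Cxcl13 and Cox6c in fibroblasts of the 4 groups; points are libraries, bars are group means, and the y axis is linear up to 10 and logarithmic above. Cxcl13 averages 228 CPM in old injured fibroblasts and 3.58 in young injured ones, while Col1a1 averages 759 CPM in old uninjured and 2578 in young uninjured fibroblasts.

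In uninjured lungs, old fibroblasts held lower levels of 14 of 28 matrix genes than young ones, though the list did not pass with an estimated correlation. Col1a1 fell by 1.76 ± 0.20, Eln, which encodes elastin, by 1.89 ± 0.27 and Col14a1, a collagen that associates with fibrils, by 1.21 ± 0.17 (edgeR adjusted p = 7.3e-05, 0.0017 and 0.00035). The list of antigen presentation through MHC class I did not pass with an estimated correlation. Of its 16 genes, 6 were higher in old fibroblasts, led by H2-Q4 at 1.53 ± 0.20 (edgeR adjusted p = 0.00019). So were Cox6c at 2.09 ± 0.21 and Npnt, an alveolar fibroblast integrin ligand, at 1.32 ± 0.25 (adjusted p = 2.9e-05 and 0.0079). Of the 28 matrix genes, 14 fell and 0 rose with age, or 20 and 0 adjusted over the list alone (camera adjusted p = 8.9e-20; adjusted p = 0.17 with an estimated correlation). Of the 20 adventitial fibroblast identity genes, which mark fibroblasts around vessels and airways, 6 fell, or 13 fell and 3 rose adjusted over the list alone, such as Col15a1 at -1.46 ± 0.22 and Mfap5 at -1.01 ± 0.16 (camera adjusted p = 8.8e-08; adjusted p = 0.11 with an estimated correlation). Collagen processing enzymes fell in 7 of 27 cases, or 10 falling and 1 rising adjusted over the list alone, such as Loxl2 at -1.41 ± 0.20 (camera adjusted p = 0.00018; adjusted p = 0.21 with an estimated correlation). Rises covered 6 of 16 MHC class I genes, or 9 adjusted over the list alone (camera adjusted p = 7.5e-09; adjusted p = 0.29 with an estimated correlation). Alveolar fibroblast identity genes rose in 5 of 22 cases, or 16 adjusted over the list alone (camera adjusted p = 3.3e-08; adjusted p = 0.41 with an estimated correlation). The list's median was 0.51 in the class but -0.25, 0.08 and 0.26 within clusters 0, 1 and 2. In the same order, adventitial identity genes had medians of 0.04, -0.29 and -0.70, against -0.75 in the class, and matrix genes -0.46, -0.85 and -0.47, against -0.99. Cluster 0, led by Pi16, held 36.3% of young and 18.1% of old uninjured fibroblasts, and cluster 2 held 9.33% and 30.7%. Oxidative phosphorylation genes rose in 8 of 26 and fell in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 4.8e-09; adjusted p = 0.29 with an estimated correlation). In all, 430 genes rose and 290 fell. Other named genes were Gja5 (2.09 ± 0.26), a gap junction protein, Ifi203, Gyg and Clec2d among the rises, and Lemd1 (-3.27 ± 0.37), Zfp185, Ppfia2 and Olfml2b (-1.93 ± 0.19) among the falls. Lif also fell, by 1.25 ± 0.26 (edgeR adjusted p = 0.0084). The same contrast in the cells outside the 3 tested classes had a median of 0.851 times the log2 change of the called fibroblast genes. There the matrix, adventitial identity and collagen processing lists had medians of -1.31, -1.10 and -0.89, with no member passing. MHC class I and oxidative phosphorylation genes had 0.95 and 0.55, while alveolar identity genes went the other way from fibroblasts, at -0.55. Plasma cell markers, among them Jchain at 4.91 ± 0.84, rose in 3 of 6 cases in the fibroblast sums, or 4 adjusted over the list alone (camera adjusted p = 0.00036; adjusted p = 0.29 with an estimated correlation). Without young uninjured library 1, young uninjured library 2 or old uninjured library 1, 413, 227 and 192 genes passed instead of 720.

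After injury, 35 genes differed between old and young fibroblasts, among them Cxcl13 and Lcn2. Cxcl13 was higher by 6.36 ± 0.44, at 228 ± 30.2 CPM against 3.58 ± 3.93, and Lcn2 by 3.53 ± 0.36, at 256 ± 25.3 CPM against 24.3 ± 15.1 (edgeR adjusted p = 6.5e-07 and 0.00075). Pla1a, a phospholipase, rose by 2.05 ± 0.34, Thsd7a by 1.97 ± 0.33 and Serpina3m, a protease inhibitor, by 1.81 ± 0.33 (adjusted p = 0.013, 0.011 and 0.020). Lum, the collagen-binding proteoglycan lumican, fell by 1.57 ± 0.22, along with Tent5c, Swt1, Ntn1 (-1.35 ± 0.21) and Frmd5 (edgeR adjusted p = 0.0041 for Lum). Saa3 and Col1a1 did not pass, at 4.04 ± 1.04 and -0.58 ± 0.19 (adjusted p = 0.41 and 0.30). Adventitial identity genes fell in 3 of 20 cases, or 11 falling and 1 rising adjusted over the list alone, such as Col14a1 at -1.19 ± 0.17 (camera adjusted p = 1.7e-13; adjusted p = 0.049 with an estimated correlation). Cluster 0 held 10.6% of young and 2.02% of old injured fibroblasts and cluster 8 held 70.1% and 86.3%. The list's median was -0.65 in the class and -0.63 within cluster 8, a test added after seeing the data. In the interferon response list, antiviral genes induced by interferons, 1 of 37 passed, Bst2 at 1.19 ± 0.21, or 12 rises adjusted over the list alone, and the list's median was 0.79 (camera adjusted p = 4.8e-19; adjusted p = 0.089 with an estimated correlation). Alveolar macrophage markers fell in 3 of 9 cases in these fibroblast sums, or 6 adjusted over the list alone, such as Chil3 at -2.45 ± 0.38 (camera adjusted p = 4.5e-11; adjusted p = 0.089 with an estimated correlation). Over all genes 18 rose and 17 fell, with a median of 0.269 times this change in the cells outside the 3 tested classes. In those cells the interferon response list had a median of 0.71 and the adventitial identity list one of -0.49. Without young injured library 2, 16 genes passed, and without old injured library 1, 73 did.

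The interaction tests whether injury acted differently on old and young fibroblasts. The injury effect on Cxcl13 was higher in old than in young fibroblasts by 6.67 ± 1.21, and that on Lgmn, a lysosomal protease, by 1.42 ± 0.26 (edgeR adjusted p = 0.030 for both). Cxcl13 had 3 counts in all old uninjured fibroblasts, so its fitted value depends on the prior count. The injury effect was lower in old fibroblasts for Ccl19, a chemokine that attracts dendritic and T cells (-2.46 ± 0.44), Ltbp4, which binds latent TGF-beta (-1.72 ± 0.31), and Cox6c (-1.56 ± 0.28), each at adjusted p = 0.030. The injury effect on Col1a1 was larger in old fibroblasts by 1.18 ± 0.27 and on Eln by 1.51 ± 0.37, and neither passed (edgeR adjusted p = 0.094 and 0.15). None of the 28 matrix genes passed over all genes, and 10 were higher and 1 lower adjusted over the list alone, with a list median of 0.62 (camera adjusted p = 3.7e-07; adjusted p = 0.43 with an estimated correlation). In the cells outside the 3 tested classes that list had a median of 1.49, with no member passing. In all, 8 genes were higher and 11 lower. With the marked doublets kept 2 genes passed, and with DESeq2 89, of which 10 were among the 19. In the cells outside the 3 tested classes, all 15 of these genes with a level there had the same sign, with a median of 0.815 times the fibroblast value. Cox6c stood at 40.8 and 28.5 CPM in young uninjured fibroblasts and at 21.9 and 32.9 in young uninjured alveolar macrophages, below its level in every other library of both classes. The count of 19 became 30 without young uninjured library 1, 6 without library 2 of that group, 5 and 3 without young injured libraries 1 and 2, 10 without old uninjured library 1 and 92 without old injured library 1.

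In alveolar macrophages, injury raised Spp1, Fabp5 and genes of cholesterol synthesis and lysosomes, and lowered Fabp1 and Acaa1b. Spp1 rose by 3.38 ± 0.19, from 327 ± 107 to 2672 ± 441 CPM in young and from 512 ± 122 to 6944 ± 518 in old lungs, and the fatty acid carrier Fabp5 rose by 2.91 ± 0.22 (edgeR adjusted p = 3e-08 and 1.5e-06). Cd63, a lysosomal membrane protein, rose by 2.61 ± 0.18, and Gpnmb, a glycoprotein of lipid-laden macrophages, by 1.55 ± 0.15. Fabp1, a fatty acid carrier of resident alveolar macrophages, fell by 3.19 ± 0.26 and Acaa1b, a peroxisomal enzyme of fat oxidation, by 2.45 ± 0.19 (edgeR adjusted p = 1.5e-06 for Fabp1). Of the 23 profibrotic macrophage genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 1.5e-21; adjusted p = 0.030 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 19 cases, or 17 adjusted over the list alone, such as Sqle by 2.41 ± 0.22 and Idi1 by 2.62 ± 0.26 (camera adjusted p = 7.9e-21; adjusted p = 0.059 with an estimated correlation). Lysosome genes rose in 20 of 28 cases, or 25 adjusted over the list alone, such as Psap by 1.60 ± 0.14 (camera adjusted p = 4.7e-18; adjusted p = 0.043 with an estimated correlation). In the cells outside the 3 tested classes, a comparison added after seeing the data, the profibrotic list rose in 18 of 25 cases and the lysosome list in 18 of 28. Of 11 interstitial macrophage genes 4 rose, among them the complement genes C1qa (2.79 ± 0.22), C1qb (3.19 ± 0.29) and C1qc (2.91 ± 0.32), or 5 rising and 1 falling adjusted over the list alone (camera adjusted p = 1.9e-07; adjusted p = 0.043 with an estimated correlation). Oxidative phosphorylation genes rose in 17 of 26 cases, or 19 adjusted over the list alone (camera adjusted p = 1.8e-11; adjusted p = 0.043 with an estimated correlation). Immediate early and heat shock genes fell in 17 of 26 cases, or 17 falling and 1 rising adjusted over the list alone, such as Egr1 at -2.35 ± 0.21 (camera adjusted p = 1.8e-09; adjusted p = 0.050 with an estimated correlation).

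Over all 8916 genes tested in alveolar macrophages, 732 rose and 747 fell with injury, and in the cells outside the 3 tested classes the called genes had a median of 0.706 times this change. Other named rises included Ch25h, Msr1, a scavenger receptor (3.20 ± 0.32), Lrg1, Lgals3bp, Hmgcs1 and Cox6c, and the remaining falls were Has1, Zfp185, Tppp3, Dnajb1, Kcnip1, Tlcd4, Tacc2, Nfix and Gpc6. Mmp12, a macrophage elastase, and the lipid receptor gene Trem2 rose by 2.55 ± 0.26 and 2.65 ± 0.35, and both are over 5 times higher in the other monocyte/macrophages. Il6ra, the interleukin 6 receptor, fell by 1.14 ± 0.22 (edgeR adjusted p = 0.0027). Slc7a2 and Odc1, the first enzyme of polyamine synthesis, stood at 0.09 ± 0.20 and 0.31 ± 0.23 (adjusted p = 0.80 and 0.37), and Arg1 and Pdgfa were too low to be tested in this class. Monocyte/macrophage markers rose in 8 of 17 cases in the alveolar macrophage sums, also adjusted over the list alone (camera adjusted p = 8.5e-12; adjusted p = 0.071 with an estimated correlation). Fibroblast markers fell in 5 of 12, or 6 adjusted over the list alone (camera adjusted p = 0.00025; adjusted p = 0.35 with an estimated correlation). Most cells of both uninjured groups were in cluster 6 and most of both injured groups in cluster 19. Without young injured library 1, 707 genes passed instead of 1479, and without young injured library 2, 906 did.

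In uninjured lungs, 3 of 9 antigen presentation genes of MHC class II were higher in old than in young alveolar macrophages. The list did not pass with an estimated correlation. Cd74, the invariant chain, rose by 2.65 ± 0.35 and H2-Aa by 2.76 ± 0.42, with Cd74 at 1533 ± 750 CPM in young and 9587 ± 435 in old macrophages (edgeR adjusted p = 0.0027 and 0.013). Ereg, a growth factor of the EGF family, fell by 3.08 ± 0.50 and Vdr, the vitamin D receptor, by 2.49 ± 0.50 (adjusted p = 0.0067 and 0.019). Clec4n, a fungal pattern receptor, fell by 2.12 ± 0.26 (edgeR adjusted p = 0.0011). Of 9 MHC class II genes 3 rose, or 6 adjusted over the list alone (camera adjusted p = 1.8e-09; adjusted p = 0.22 with an estimated correlation). Of 15 MHC class I genes 2 rose, Tap2 (2.29 ± 0.41) and H2-T22, or 5 adjusted over the list alone (camera adjusted p = 4e-05; adjusted p = 0.22 with an estimated correlation). Markers of plasma cells rose in 3 of 5 cases in these sums, also adjusted over the list alone, such as Igkc at 3.75 ± 0.42 (camera adjusted p = 7.1e-06; adjusted p = 0.22 with an estimated correlation). Over all genes 106 rose and 48 fell, among them Dcaf13, Col4a2 (2.25 ± 0.34), ENSMUSG00000079808 and Pex5, which rose, and Tmem53, Kcnc1 and Zfp185, which fell. Tmem53 was also higher in young than in old uninjured fibroblasts, at 244 and 478 CPM against 24.7 and 63.4, and in dendritic cells, at 298 and 379 CPM against 37.6 and 94.1. The called genes had a median of 0.663 times this change in the cells outside the 3 tested classes. The count of 154 became 77 without young uninjured library 2, 72 and 81 without young injured libraries 1 and 2, 16 without old uninjured library 1 and 260 without old uninjured library 2.

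After injury, some interferon response and complement genes were higher, and some genes of alveolar macrophage identity lower, in old than in young alveolar macrophages. None of the lists that hold them passed with an estimated correlation. Apoe, which carries lipids, rose by 2.18 ± 0.23, from 337 ± 68.3 to 1522 ± 91.9 CPM, Spp1 by 1.38 ± 0.25, and C1qb by 1.78 ± 0.32 (edgeR adjusted p = 0.0001, 0.0086 and 0.0090). Chil3, a chitinase-like protein, fell by 1.46 ± 0.24, Plet1, a surface protein of alveolar macrophages, by 1.40 ± 0.24 and Clec4n by 2.59 ± 0.26 (adjusted p = 0.0056, 0.0068 and 0.0001). Of 23 alveolar macrophage identity genes 5 fell, or 11 adjusted over the list alone (camera adjusted p = 2e-07; adjusted p = 0.26 with an estimated correlation). Interferon response genes rose in 5 of 21 cases, or 6 adjusted over the list alone, such as Ifi27l2a by 1.79 ± 0.25 and Oasl2 by 3.36 ± 0.53 (camera adjusted p = 2.4e-08; adjusted p = 0.19 with an estimated correlation). The 3 complement genes C1qa, C1qb and C1qc were the interstitial macrophage genes that rose, 3 of 11, or 4 adjusted over the list alone (camera adjusted p = 5.9e-05; adjusted p = 0.19 with an estimated correlation). ER chaperones fell in 2 of 20 cases, or 11 adjusted over the list alone, such as Pdia3 at -1.24 ± 0.22 (camera adjusted p = 7.2e-07; adjusted p = 0.26 with an estimated correlation). Other named genes were Col4a2 (3.40 ± 0.32), Adgrv1, Cmbl, Mirt1 and Itga9 among the rises, and Prelid3b, Dgat2, Tle4 and Btbd19, each with 1 to 3 counts in old injured cells, among the falls. Monocyte/macrophage markers rose in 5 of 17 cases, or 8 rising and 1 falling adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.35 with an estimated correlation). Apoe and the 3 complement genes are on that marker list as well. Neutrophil markers rose in 2 of 8, or 4 adjusted over the list alone, led by S100a9 at 3.02 ± 0.57 (camera adjusted p = 0.00048; adjusted p = 0.35 with an estimated correlation). In all, 177 genes rose and 118 fell, in sums over 26 and 50 cells in the old injured libraries, with a median of 0.0691 times this change in the cells outside the 3 tested classes. The lists named above moved in those cells too. Their medians there were 0.71 for interferon response, 0.59 for interstitial macrophage, -0.92 for alveolar macrophage identity and -0.39 for ER chaperone genes. The count of 295 became 28 and 64 without young injured libraries 1 and 2, 477 without old uninjured library 2 and 110 without old injured library 1.

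Injury acted differently on old and young alveolar macrophages for a small set of genes. For Chil3 the injury effect was lower in old macrophages, a difference of -1.73 ± 0.34, with 698 ± 218 and 3856 ± 382 CPM in young uninjured and injured and 844 ± 152 and 1400 ± 120 in old ones (edgeR adjusted p = 0.037). The respiratory chain genes Ndufb9 (-2.10 ± 0.44) and Cox6a1 (-1.95 ± 0.41) and the lysosomal sorting receptor M6pr (-1.74 ± 0.36) also had lower injury effects in old cells, and Mirt1 (3.84 ± 0.55) a higher one (adjusted p = 0.040, 0.040, 0.039 and 0.018). Of the 23 identity genes, 1 was lower in the difference, or 7 adjusted over the list alone (camera adjusted p = 4.5e-05; adjusted p = 0.34 with an estimated correlation). Fibroblast markers were higher in the difference for 1 of 12, Col1a2 at 3.22 ± 0.61, or 3 adjusted over the list alone (camera adjusted p = 3.6e-07; adjusted p = 0.34 with an estimated correlation). In all, 30 genes were higher and 21 lower, with a median of 0.475 times this difference in the cells outside the 3 tested classes. Without old uninjured library 1 no gene passed in edgeR (0 genes, with 1154 at an unadjusted p under 0.05). The count of 51 became 21 without young uninjured library 2, 13 and 15 without young injured libraries 1 and 2, 198 without old uninjured library 2 and 115 without old injured library 2.

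**Figure D2:**
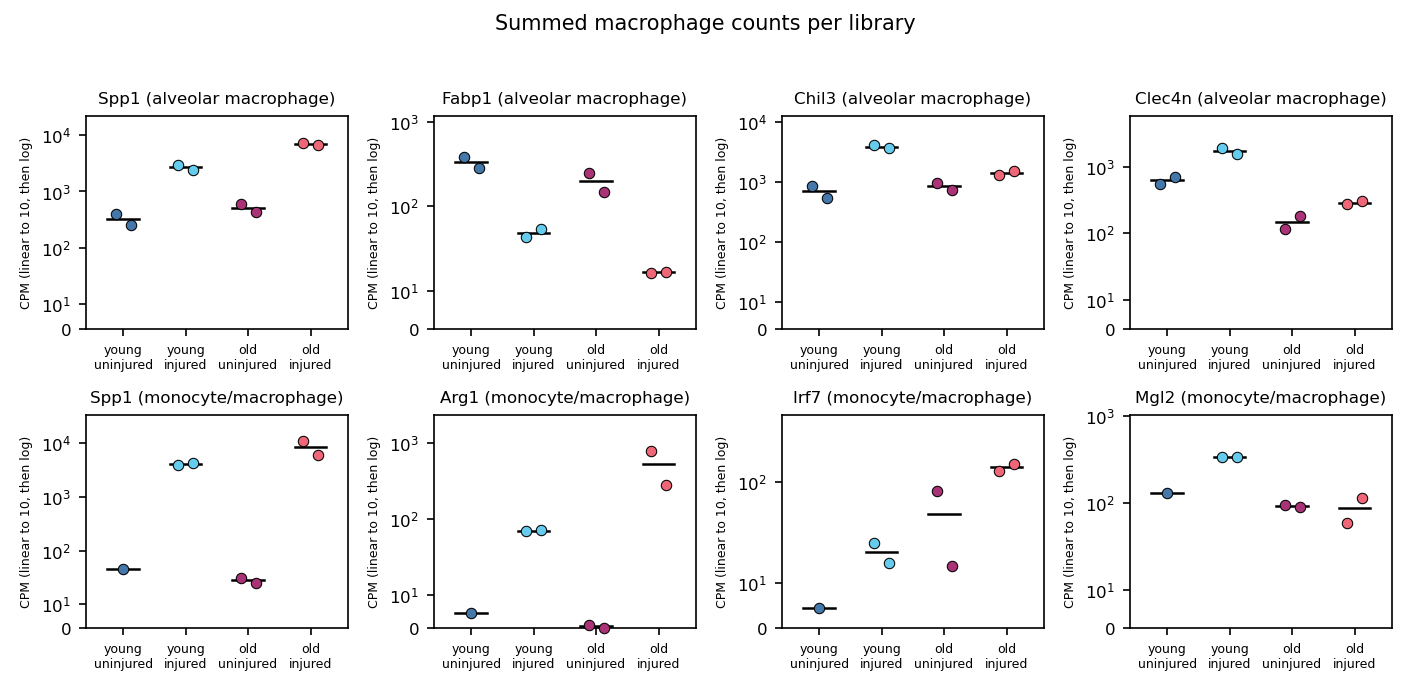
Levels in CPM of Spp1, Fabp1, Chil3 and Clec4n in alveolar macrophages and of Spp1, Arg1, Irf7 and Mgl2 in other monocyte/macrophages; points are libraries, bars are group means, the y axis is linear up to 10 and logarithmic above, and young uninjured monocyte/macrophages are 1 library. Spp1 in alveolar macrophages averages 327 CPM in young uninjured and 6944 in old injured lungs.

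In monocyte/macrophages other than alveolar macrophages, injury raised genes of the profibrotic macrophage and lysosome lists. Spp1 rose by 7.32 ± 0.37 and Gpnmb by 5.47 ± 0.35, and in old lungs Spp1 went from 28.0 ± 4.34 to 8402 ± 3525 CPM (edgeR adjusted p = 2.1e-09 and 6e-08). Trem2 rose by 3.48 ± 0.30, Mmp12 by 2.82 ± 0.30 and Pdgfa, a growth factor for fibroblasts, by 1.30 ± 0.27 (adjusted p = 9.9e-07, 3.6e-05 and 0.0025). Arg1, which splits arginine into ornithine and urea, had 1 count in each uninjured group and 69.7 ± 1.91 CPM in young injured and 526 ± 354 in old injured cells (edgeR adjusted p = 0.010). Genes of circulating monocytes fell, among them Ifitm6 at -3.78 ± 0.21, Adgre4 at -3.39 ± 0.42 and Plac8 at -2.68 ± 0.28 (edgeR adjusted p = 6.4e-09 for Ifitm6). Il6ra fell by 1.44 ± 0.18 (edgeR adjusted p = 4e-05). Of 25 profibrotic macrophage genes 22 rose, or 23 adjusted over the list alone, such as Fabp5 by 4.92 ± 0.32 (camera adjusted p = 8.7e-57; adjusted p = 0.18 with an estimated correlation). Lysosome genes rose in 24 of 28 cases, and in 28 adjusted over the list alone, such as Ctsd by 3.11 ± 0.23 (camera adjusted p = 6.2e-32; adjusted p = 0.21 with an estimated correlation). Of 17 monocyte genes 9 fell and 4 rose, also adjusted over the list alone, such as Ly6c2 at -1.81 ± 0.22 (camera adjusted p = 1.8e-08; adjusted p = 0.33 with an estimated correlation).

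Inflammatory cytokine genes rose in 12 of 25 cases in injured monocyte/macrophages, or 13 adjusted over the list alone, among them Il1rn (2.00 ± 0.22), the interleukin 1 receptor antagonist, Ccl2 (1.87 ± 0.23) and Osm (1.80 ± 0.24) (camera adjusted p = 3.2e-07; adjusted p = 0.21 with an estimated correlation). Arginine, ornithine and proline genes rose in 8 of 20 cases, or 9 adjusted over the list alone, such as the arginine transporter Slc7a2 by 2.65 ± 0.38, the citrulline enzyme Ass1 by 2.16 ± 0.39 and Odc1 by 1.11 ± 0.22 (camera adjusted p = 0.0079; adjusted p = 0.39 with an estimated correlation). Slc7a2 is over 5 times higher in alveolar macrophages. Glycolysis genes rose in 11 of 24 cases and fell in 1, or 13 and 1 adjusted over the list alone, led by Hk2 at 2.52 ± 0.25 (camera adjusted p = 7.4e-06; adjusted p = 0.39 with an estimated correlation). Oxidative phosphorylation genes rose in 21 of 26 cases and fell in 1, or 22 and 1 adjusted over the list alone (camera adjusted p = 7.6e-18; adjusted p = 0.28 with an estimated correlation). Cell cycle genes rose in 24 of 40 cases, or 33 rising and 1 falling adjusted over the list alone (camera adjusted p = 1.1e-09; adjusted p = 0.39 with an estimated correlation). These lists also rose in the cells outside the 3 tested classes, a comparison added after seeing the data. There inflammatory cytokine genes rose in 10 of 26 cases and arginine, ornithine and proline genes in 7 of 18. Glycolysis genes rose there in 12 of 25, oxidative phosphorylation genes in 21 of 26 and cell cycle genes in 12 of 34. Over all 13442 genes tested, 1754 rose and 867 fell, with a median of 0.479 times this change in the cells outside the 3 tested classes. Several genes with the largest rises had 0 counts in the young uninjured library, such as Syngr1, at least 6.65-fold higher in young injured and at least 9.13-fold higher in old injured cells with a floor of 3 counts over the group, and Galns, Tmem86a, Slc27a1, Slc36a2, Ccna2, Comtd1, Polr2g and Mrps36. The other named falls were Krt80, Treml4, Smad3, Ccdc88c, Vcam1, Itgal, Grk5, Gpr141 and Ifitm3. Fibroblast markers fell in 4 of 13 cases and rose in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.54 with an estimated correlation). Cluster 17 was the largest in both uninjured groups, while clusters 3 and 5 held most young injured cells and clusters 5 and 12 most old injured cells.

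After injury, some interferon response and monocyte genes were higher, and some cholesterol synthesis and MHC class II genes lower, in old than in young monocyte/macrophages. None of these lists passed with an estimated correlation. Irf7, a transcription factor of the interferon response, rose by 2.73 ± 0.40, from 20.5 ± 6.45 to 140 ± 17.5 CPM, and the antiviral gene Rtp4 by 2.63 ± 0.32 (edgeR adjusted p = 0.023 and 0.00073). Ly6c2 and Plac8, both high in circulating monocytes, rose by 2.59 ± 0.26 and 2.59 ± 0.33 (adjusted p = 0.00013 and 0.0016). Mgl2, a lectin induced by interleukin 4, fell by 2.02 ± 0.26 and Dcstamp, which drives cell fusion, by 1.52 ± 0.30 (edgeR adjusted p = 0.00099 and 0.028). Of 38 interferon response genes 15 rose, or 33 adjusted over the list alone (camera adjusted p = 1.1e-60; adjusted p = 0.12 with an estimated correlation). Of 17 monocyte genes 7 rose, or 9 adjusted over the list alone, with Ms4a4c at 2.49 ± 0.29 and Vcan at 1.83 ± 0.30 (camera adjusted p = 2.5e-23; adjusted p = 0.12 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 20 cases, or 16 adjusted over the list alone, such as Cyp51 at -1.66 ± 0.32 (camera adjusted p = 2.7e-24; adjusted p = 0.12 with an estimated correlation). MHC class II genes fell in 5 of 10 cases, or 8 adjusted over the list alone, such as H2-Ab1 at -1.18 ± 0.23 (camera adjusted p = 2.5e-18; adjusted p = 0.10 with an estimated correlation). Cell cycle genes fell in 2 of 40 cases, or 7 adjusted over the list alone, with Mki67 at -1.17 ± 0.22 (camera adjusted p = 6.8e-17; adjusted p = 0.18 with an estimated correlation). Within clusters 3, 5, 12 and 13 the medians were 0.61, 1.11, 1.10 and 0.80 for interferon response and -1.16, -0.96, -0.90 and -1.02 for cholesterol synthesis, against 1.24 and -0.96 in the class. For MHC class II they were -0.11, -0.41, -0.88 and -0.44, against -0.94 in the class. Monocyte genes had 0.22, 1.31, 1.28 and 0.30, and cell cycle genes 0.43, -0.14, -0.23 and -0.03. Clusters 3, 12 and 13 held 30.2, 12.9 and 17.8% of young and 6.82, 30.2 and 7.89% of old injured cells.

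Of the genes linked to fibrosis, Arg1, Spp1 and Gpnmb were not called between old and young injured monocyte/macrophages, at 2.93 ± 0.52, 1.06 ± 0.27 and 0.84 ± 0.26 (edgeR adjusted p = 0.12, 0.087 and 0.22). The Arg1 value was 1.95 without old injured library 1 and 3.50 without library 2, fits that leave 1 old injured library. Among the 25 profibrotic macrophage genes, Ctsl (1.58 ± 0.22) and Cd36 rose and Itgax fell, or 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 7.5e-07; adjusted p = 0.38 with an estimated correlation). Slc7a2 fell by 1.17 ± 0.24 (edgeR adjusted p = 0.026). Other named genes included Ly6i (2.50 ± 0.37), which rose, and H2-M2 (-3.27 ± 0.55) and the leukotriene enzyme Alox5 (-1.56 ± 0.27), which fell. In all, 68 genes rose and 51 fell, with a median of 0.610 times this change in the cells outside the 3 tested classes. Neutrophil markers rose in 2 of 9 cases in these sums, or 4 rising and 1 falling adjusted over the list alone, such as S100a9 at 2.59 ± 0.35 (camera adjusted p = 4.1e-07; adjusted p = 0.24 with an estimated correlation). The count of 119 became 58 without young injured library 2, 219 and 215 without old uninjured libraries 1 and 2, and 195 and 211 without old injured libraries 1 and 2.

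**Figure D3:**
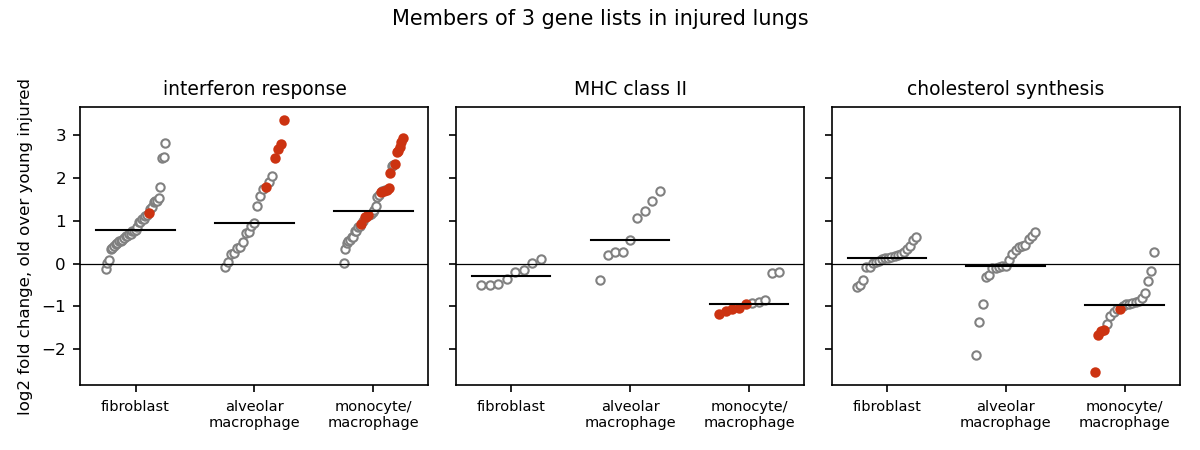
Log2 fold changes, old over young in injured lungs, of the members of the interferon response, MHC class II and cholesterol synthesis lists in the 3 tested classes; each point is a gene, red points have an edgeR adjusted p under 0.05, and the line is the list median. In monocyte/macrophages the interferon response median is 1.24 and those of MHC class II and cholesterol synthesis are -0.94 and -0.96.

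In uninjured lungs, few monocyte/macrophage genes passed between old and young cells, where the young group is 1 library of 66 cells, so that its spread is taken from the other groups. Itgb7, an integrin chain of leukocyte homing, rose by 3.65 ± 0.50 and Ly6c2 by 2.10 ± 0.36 (edgeR adjusted p = 0.0019 and 0.014). Psmb9, an immunoproteasome subunit with 0 counts in the young library, was at least 4.04-fold higher in old cells. Cxcl1, a neutrophil chemokine, fell by 2.63 ± 0.43, Mt2, a metallothionein, by 2.25 ± 0.32, and Flrt3 and Sh3pxd2a fell as well (edgeR adjusted p = 0.0075 for Cxcl1 and 0.0026 for Mt2). Without the 5% of cells with the highest doublet scores Cxcl1 turned to 0.21, and without cluster 5 it was -0.28, and neither passed. Tafa2 fell by 7.47 ± 0.40, and its level was high in every cell class of young uninjured library 1. Of 16 MHC class I genes 1 rose, or 11 adjusted over the list alone (camera adjusted p = 1.5e-10; adjusted p = 0.65 with an estimated correlation). Of 10 MHC class II genes 0 passed, or 7 rose adjusted over the list alone (camera adjusted p = 3.3e-08; adjusted p = 0.34 with an estimated correlation). In all, 12 genes rose and 21 fell, with a median of 0.524 times this change in the cells outside the 3 tested classes. The count of 33 became 63 and 65 without young injured libraries 1 and 2, 16 and 434 without old uninjured libraries 1 and 2, and 145 and 181 without old injured libraries 1 and 2, and it was 141 with DESeq2. Cluster 17 held 42.2% of young and 71.8% of old uninjured cells, and cluster 11 held 25.3% and 8.63%. With the 17 cells of young uninjured library 2 added 184 genes passed, 23 of them among the 33.

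In monocyte/macrophages the injury effect differed between old and young cells for 4 of 10 MHC class II genes, among others. The list did not pass with an estimated correlation, and single clusters were not tested for this contrast. Cluster 3 held 30.2% of young and 6.82% of old injured cells, and cluster 17 held 42.2% of young and 71.8% of old uninjured ones. The injury effect was lower in old cells for H2-Aa, an MHC class II chain, with a difference of -2.44 ± 0.42, for Cd74 (-2.17 ± 0.41), for H2-Eb1 (-2.17 ± 0.39) and for H2-DMb1 (-2.05 ± 0.39) (edgeR adjusted p = 0.032, 0.034, 0.032 and 0.034). H2-Aa stood at 513 CPM in the young uninjured library, 2291 ± 256 in young injured, 1448 ± 406 in old uninjured and 1203 ± 87.8 in old injured cells. Of the 10 MHC class II genes 4 were lower in the difference, or 8 adjusted over the list alone (camera adjusted p = 1.8e-22; adjusted p = 0.081 with an estimated correlation). With the 17 cells of young uninjured library 2 added H2-Aa passed at -2.35, and it did not pass without the highest doublet scores, at -2.28, or without cluster 5, at -2.12. The injury effect was higher in old cells for the platelet factor gene Pf4 (2.11 ± 0.41), Rgl1 and Cxcl1 (2.65 ± 0.48) and lower for Itgb7, Tppp3, Pilra and Mcemp1 (-2.54 ± 0.46). Cxcl1 turned to -0.27 without the highest doublet scores and to -0.46 without cluster 5, and Pf4 passed in neither setting, nor with the second young library added (1.84) or with doublets kept (1.49). In all, 12 genes were higher and 13 lower, again with 1 young uninjured library, and with its second library added 30 passed, 14 of them among the 25. The median in the cells outside the 3 tested classes was 0.158 times this difference. The count of 25 became 13 and 227 without old uninjured libraries 1 and 2, and 50 and 78 without old injured libraries 1 and 2.

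Shares of the immune cells were compared for 6 classes. Monocyte/macrophages made up 14.3 ± 2.61% of immune cells in young uninjured, 46.4 ± 4.06% in young injured, 31.2 ± 9.44% in old uninjured and 66.8 ± 8.54% in old injured lungs. They were 33.9 percentage points higher in the 4 injured than in the 4 uninjured libraries (two-sided exact permutation test, p = 0.0286, the smallest its 70 arrangements can give; adjusted p = 0.171). Alveolar macrophages held 56.9 ± 9.38%, 24.5 ± 1.37%, 25.5 ± 3.87% and 4.96 ± 2.23% in the same order of groups, 26.5 points fewer after injury as a difference of -26.5 (exact permutation p = 0.0857, adjusted p = 0.257). Dendritic cells made up 20.2 and 19.7% in the 2 young uninjured libraries and 18.6 ± 0.313% in young injured lungs. In old lungs they were 8.95 ± 1.43% and 9.65 ± 1.52%, a difference with age of -9.97 points (exact permutation p = 0.0286, adjusted p = 0.0857). That difference was -4.88 with the marked doublets kept and -5.39 at clustering resolution 0.5, where fewer cells are named dendritic. Neutrophils were 2.82 points and T cells 8.56 points more frequent in old libraries (exact permutation p = 0.0286 and 0.0571, adjusted p = 0.0857 and 0.114). No share passed after adjustment over the 6 classes. With edgeR's quasi-likelihood test on cell counts instead, alveolar macrophages (-1.78 ± 0.23) and monocyte/macrophages (1.38 ± 0.19) passed with injury (adjusted p = 0.000766 for both) and 5 classes passed with age. The CD45 selection sets which cells enter these shares, and the fibroblast share of all cells, 68.5% in young uninjured and 12.9% in old injured lungs on average, is set by the mixing of the separate preparations and was not tested.

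**Figure D4:**
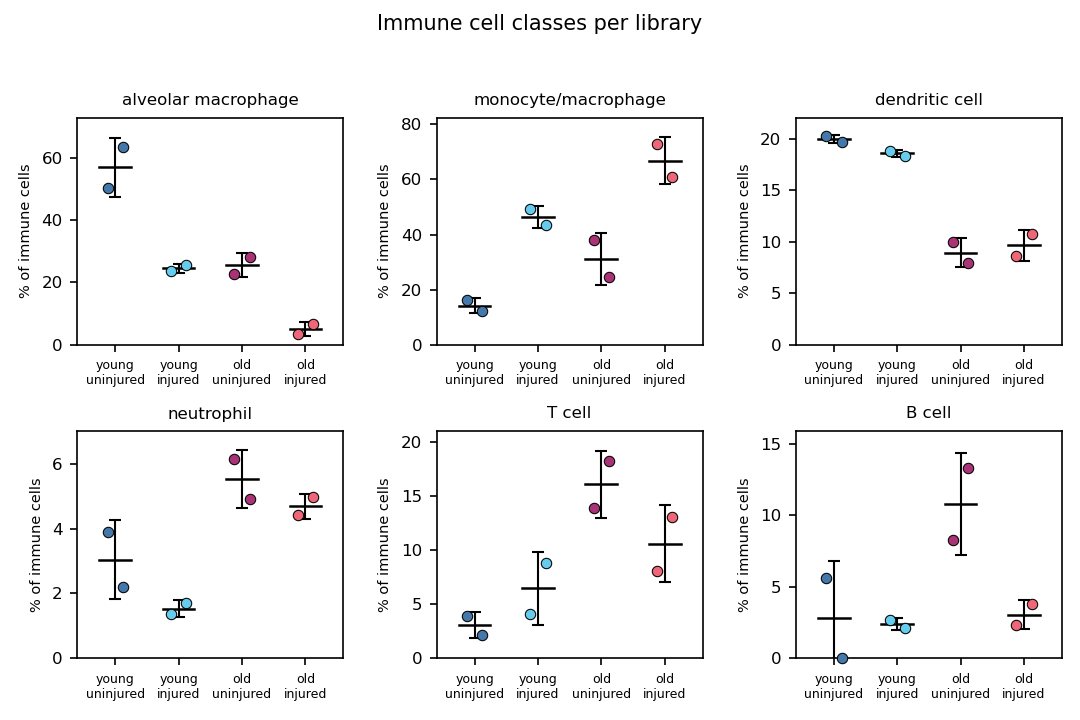
Percent of immune cells in each of 6 classes by group; points are libraries and lines are mean ± SD over the 2 libraries of a group. Monocyte/macrophages average 14.3% in young uninjured and 66.8% in old injured lungs, and alveolar macrophages 56.9% and 4.96%.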

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

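The comparison of the unnamed barcodes with the rest of their library was a test chosen only after the result was seen, and the interaction tests were planned. Each gene below stands out because its injury effect differs between old and young mice by the interaction test. Values are that difference as log2 ± SE, with the injury effect in young and then old mice in brackets, over 2 libraries per group except where 1 is named.

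In fibroblasts, with adjusted p from 0.024 to 0.030, Cxcl13 stood at 6.67 ± 1.21 (1.28 and 7.95), with 3 counts in all old uninjured fibroblasts, so that its fitted value depends on the prior count. Ppfia2 stood at 4.16 ± 0.59 (-3.12 and 1.04), Zfp185 at 3.01 ± 0.48 (-4.27 and -1.26) and S100a10, a calcium-binding protein, at 1.55 ± 0.28 (-0.80 and 0.74). Lgmn, a lysosomal protease, was at 1.42 ± 0.26 (0.18 and 1.61). Lower injury effects in old mice were found for the chemokine gene Ccl19 at -2.46 ± 0.44 (3.21 and 0.75), Ifi203, an interferon-inducible gene, at -1.90 ± 0.35 (1.31 and -0.59) and Ltbp4 at -1.72 ± 0.31 (0.61 and -1.11). Gyg, which starts glycogen chains, was at -1.57 ± 0.28 (1.66 and 0.09) and Cox6c of the respiratory chain at -1.56 ± 0.28 (2.94 and 1.38). Both young uninjured libraries stood apart from all others in alveolar macrophages too, with Cox6c at 21.9 and 32.9 CPM and Zfp185 at 196 and 147. With the marked doublets kept, 2 of the 19 fibroblast genes passed.

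In alveolar macrophages, with adjusted p from 0.018 to 0.040, higher injury effects in old mice were found for Mirt1 at 3.84 ± 0.55 (-1.86 and 1.99) and Stk32b at 3.05 ± 0.62 (-1.95 and 1.10). Sh3rf3 was at 2.87 ± 0.57 (-1.87 and 1.01) and Klhl29 at 2.77 ± 0.54 (-2.17 and 0.60). Lower ones were found for the respiratory chain genes Ndufb9 at -2.10 ± 0.44 (2.72 and 0.61) and Cox6a1 at -1.95 ± 0.41 (2.42 and 0.47), and for Pon2, a lactonase, at -1.77 ± 0.36 (1.28 and -0.49). M6pr, the lysosomal sorting receptor, was at -1.74 ± 0.36 (1.70 and -0.04) and Chil3, the chitinase-like protein, at -1.73 ± 0.34 (2.46 and 0.73). Without old uninjured library 1, 0 genes passed in edgeR in this class, with 1154 at an unadjusted p under 0.05.

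In monocyte/macrophages, where young uninjured is 1 library, adjusted p ran from 1.5e-06 to 0.041. Tafa2 stood at 7.56 ± 0.57 (-7.49 and 0.06), and its level in alveolar macrophages was 1557 CPM in young uninjured library 1 and 30.4 in library 2. Higher injury effects in old mice were also found for the chemokine gene Cxcl1 at 2.65 ± 0.48 (-0.02 and 2.63), Rgl1 at 2.33 ± 0.40 (-1.74 and 0.59) and Pf4 at 2.11 ± 0.41 (-1.20 and 0.92). The Cxcl1 difference turned to -0.27 without the highest doublet scores and to -0.46 without cluster 5, both settings chosen after seeing the data. Lower ones were found for the integrin gene Itgb7 at -3.08 ± 0.57 (1.07 and -2.01), Tppp3 at -3.01 ± 0.57 (1.60 and -1.41) and Pilra at -2.77 ± 0.54 (2.40 and -0.37). Mcemp1 was at -2.54 ± 0.46 (1.42 and -1.12) and the MHC class II chain gene H2-Aa at -2.44 ± 0.42 (2.16 and -0.28).

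The 122 barcodes without a class, all from old injured library 2, are in no comparison, and 61.4% of their counts are in 3185 genes over 5 times higher in them than in the rest of that library, where these genes hold 2.05%. That share is raised by the choice of genes. With 2592 genes picked on 61 of the barcodes and counted in the other 61, it was 29.2%, against 1.91% in the rest. For as many random barcodes of the rest, 272 genes were picked in the same way and held 0.121%, against 0.153%. Their median was 1477.5 counts per barcode, against 2623.5 in the rest, with 0.368 and 1.66% of counts from mitochondrial genes. The vitamin transporter gene Slc5a6 was at 11684 CPM in them and 108 in the rest, the transcription factor gene Sim1 at 10604 and 195, and the cadherin gene Cdh13 at 10668 and 594.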

How the results depend on the processing

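The tests without the 5% of cells with the highest doublet scores, without a minimum number of cells and without cluster 5 were chosen after seeing the data, and every other alternative was planned. Of 285 counts under an alternative, 206 stayed within 1.5 times the main count and 79 did not. Of 5057 comparisons of single named genes, 4679 kept direction and call, 330 lost the call, 44 gained it and 4 reversed. Among 266 results for named genes, 96 of the 180 called ones were called in every setting that gave a value. Of 3739 comparisons of gene lists, 3314 kept direction and call, 125 gained a call, 296 lost it, of which 157 with the estimated correlation, and 4 reversed. The injury count of monocyte/macrophages, 2621, stayed within 1.5 times in every setting that gave one, as did all 15 counts at resolution 2 and 12 of 13 with RLE scaling. The calls for genes named by rank, 159 of the 180, also did, from 112 to 146 over the 6 omissions that leave every class with all contrasts. Where no reason is given below, the cause was not tested.

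With DESeq2, injury changed 3103 fibroblast genes (4663 in edgeR) and 960 alveolar macrophage genes (1479). Its interaction counts were 89 (19), 111 (51) and 57 (25) in fibroblasts, alveolar and monocyte/macrophages, and its count for age in uninjured monocyte/macrophages was 141 (33). Without the filter on low counts, more genes are tested. Age in injured lungs then gave 168 genes in fibroblasts (35), 759 in alveolar macrophages (295) and 302 in monocyte/macrophages (119), age in uninjured lungs gave 365 (154) and 156 (33) in the 2 macrophage classes, and the interaction gave 116, 386 and 91 in the 3 classes. With genes higher in another class removed, so that fewer were tested, the interaction gave 34 fibroblast and 32 alveolar macrophage genes and age in uninjured lungs 72 monocyte/macrophage genes. With the marked doublets kept, the fibroblast interaction fell to 2 genes.

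Age in uninjured monocyte/macrophages, 33 genes with 1 young library, moved most often: 50 with RLE scaling, 83 with the strict cell filter, 95 with every deposited barcode, 251 with doublets kept, 240 at resolution 0.5 and 184 without a minimum number of cells. The last brings back the second young library (17 cells), and so do the 2 before it (25 cells), in which the class also gains cells where the dendritic class loses them (509 to 600 and 194 to 101 in young injured library 1 with doublets kept). The monocyte/macrophage interaction gave 12 genes without the highest doublet scores and 14 without cluster 5. Of the gene list tests, 162 passed camera and 5 passed with an estimated correlation. No share passed the permutation test, and with edgeR on cell counts 2 passed with injury and 5 with age.

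Whether the replicate numbers pair the libraries was not settled. Correlations of replicate differences between groups ran from -0.045 to 0.136. Between old uninjured and old injured libraries they were 0.102 in fibroblasts, 0.136 in alveolar macrophages and 0.110 in monocyte/macrophages, just above the preset limit of 0.1. As a block, the replicate numbers gave 257, 458 and 196 genes in alveolar macrophages for age in uninjured lungs, age in injured lungs and the interaction, and 124, 236 and 40 in monocyte/macrophages.

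With 1 library left out, the lone library of its group is assumed to vary like the other groups. Counts ran from 2975 to 4598 for injury in fibroblasts, from 192 to 845 for age in uninjured lungs, from 16 to 73 for age in injured lungs and from 3 to 92 for the interaction. The same 4 counts ran from 707 to 1560, 16 to 260, 28 to 477 and 0 to 198 in alveolar macrophages. The 0, without old uninjured library 1, stands beside 1154 genes at an unadjusted p under 0.05 in edgeR, and DESeq2 was not run without that library. In monocyte/macrophages they ran from 1983 to 3139, 16 to 434, 58 to 219 and 13 to 227. Gene list tests ran from 145 to 170, and no share passed with any library left out, which says little, since the smallest p of that test is 0.0286 and 6 classes are adjusted for. Without young uninjured library 1, monocyte/macrophages have no young uninjured library, so that only age in injured lungs gave a value (108). The number of gene list tests without a young uninjured library is not given, since monocyte/macrophages then lack contrasts or are the same sums. Gene list tests were not run with RLE scaling, DESeq2 or no filter on low counts.

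Without the highest doublet scores, Cxcl1 in monocyte/macrophages turned to 0.21 for age in uninjured lungs (-2.63 in full) and to -0.27 for the interaction (2.65 in full), and without cluster 5 the interaction was -0.46. The adjusted p were 0.94, 0.94 and 0.82, in ranges over the alternatives from 2.8e-05 to 0.94 for age and 0.00084 to 0.94 for the interaction. Mmp12 between old and young injured monocyte/macrophages was 0.08 in full and -1.29 without cluster 5 (adjusted p = 0.013, range 0.013 to 1). Of the lists, fibroblast markers in uninjured alveolar macrophages reversed without old uninjured library 1 (camera adjusted p = 0.988, range 1.6e-10 to 0.988). In injured monocyte/macrophages with age, inflammatory cytokines (0.994, range 1.4e-06 to 0.994) and lysosome genes (0.85, range 0.00012 to 0.85) reversed without old injured library 1, and arginine, ornithine and proline genes (0.0277, range 0.0277 to 0.991, and up to 0.859 with 1 library left out) without old injured library 2.

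The smallest sums were of 26 and 50 old injured alveolar macrophages and of 66 young uninjured monocyte/macrophages in 1 library. On simulated counts 63.9% of 2-fold changes were recovered in fibroblasts, 38.0% in alveolar macrophages and 24.5% in monocyte/macrophages, so smaller changes are missed, and depth was not separated from the number of libraries.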

Other observations

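The tests of dendritic cells and of the cells outside the 3 tested classes, the splits of the libraries, the Arg1 test with 1 library left out and both tests on fibroblast age were chosen only after the results were seen.

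Dendritic cell-like cells, which present antigen to T cells, were tested as a class of their own with 2 libraries per group. With doublets kept or at resolution 0.5 the class shrinks, from 194 to 101 and 103 cells in young injured library 1, and its genes were not tested there. Cluster 4, led by Cd209a and Ccl17, held 33 and 8 cells of the young uninjured and 90 and 71 of the young injured libraries, and cluster 7, led by Timd4 and Clec9a, 44 and 15 and then 60 and 45. Injury raised Spp1, the gene of osteopontin, by 3.11 ± 0.28 and Gpnmb by 1.98 ± 0.48, both over 5 times higher in another class (edgeR adjusted p = 8e-08 and 0.0047). Of 25 oxidative phosphorylation genes 17 rose, or 18 adjusted over the list alone (camera adjusted p = 2.2e-11; adjusted p = 0.14 with an estimated correlation). Of 19 profibrotic macrophage genes 10 rose and 2 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 4.3e-07; adjusted p = 0.19 with an estimated correlation). Of 26 immediate early and heat shock genes 14 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 3.6e-05; adjusted p = 0.19 with an estimated correlation). Over 6118 genes 621 rose and 560 fell. Without young injured library 2, 765 genes passed instead of 1181, and DESeq2 gave 709.

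Between old and young injured dendritic cells, the lectin gene Cd209a fell by 1.71 ± 0.28 and the chemokine gene Ccl22 by 1.36 ± 0.28 (edgeR adjusted p = 0.0030 and 0.021), while Ccl17 stood at -0.94 ± 0.61 (adjusted p = 0.89). Of 11 genes of the response to interleukins 4 and 13, 3 fell, or 4 falling and 1 rising adjusted over the list alone (camera adjusted p = 1.1e-05; adjusted p = 0.11 with an estimated correlation). Alveolar macrophage identity genes fell in 1 of 12 cases, or 7 adjusted over the list alone, with a median of -1.35 (camera adjusted p = 9.6e-11; adjusted p = 0.14 with an estimated correlation), while monocyte genes rose in 2 of 13, or 4 rising and 2 falling adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.00098; adjusted p = 0.25 with an estimated correlation). None of 14 interferon response genes passed, or 2 rose adjusted over the list alone, with a list median of 0.75 (camera adjusted p = 1.3e-06; adjusted p = 0.22 with an estimated correlation). In all 14 genes rose and 12 fell. Without young injured library 2, 6 genes passed instead of 26, without old injured library 2, 17, and DESeq2 gave 12.

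For injury, 1 of the 35 splits of the libraries into groups of the same sizes, the real one, gave as many genes in each class. This argues against a random grouping of the libraries, though 1 of 35 is the strongest result the test can give. Every other split mixes injured with uninjured libraries, so the test cannot tell injury from other differences between these libraries. The real split gave 3600 fibroblast genes, 815 in alveolar macrophages and 1821 in monocyte/macrophages, and the highest other gave 0, 60 and 0. In the same order, the called genes had medians of 0.741, 0.706 and 0.479 times the class's change in the cells outside the 3 tested classes.

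Interferon response genes were higher in old than in young injured monocyte/macrophages, with a list median of 1.24 (camera adjusted p = 1.1e-60; adjusted p = 0.12 with an estimated correlation). A different mix of clusters as the whole cause is argued against by medians of 0.61 to 1.11 within 4 clusters (median 0.95, bound 0.619). Mix as a part stays open, as cluster 12, with Irf7 a leading gene, made up more of the old cells. A single library is argued against as well, as the lowest median with 1 injured library left out was 1.02. RNA from neutrophils, whose share was read as 1.70% from S100a8 and S100a9 (127 and 117 CPM in the old class, 5923 and 9366 in old neutrophils), would bring 2.98% of the rise of the median member, under the bound of 10. A difference shared by all cells of a library stays open, the list's median being 0.75 in injured dendritic cells. The 0.71 in injured and 0.96 in uninjured cells outside the 3 tested classes cannot decide it, as their mix differs with age. Age stays open too, untested apart from the libraries.

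Arg1 stood 2.93 ± 0.52 higher in old than in young injured monocyte/macrophages without passing (edgeR adjusted p = 0.12, and up to 0.64 over the alternatives). A larger share of cluster 5 in old lungs as the whole cause is argued against by 2.54 ± 0.69 within that cluster, beside 0.51 ± 0.61, 3.70 ± 0.51 and 2.60 ± 0.24 in clusters 3, 12 and 13, of which the last 2 passed. A single library as the whole cause is argued against by the lowest value with 1 injured library left out, 1.95 without old injured library 1. The value was 3.50 without old injured library 2. Both fits leave 1 old injured library, so the spread between the 2 old libraries is not in them and only the effect sizes are read. A difference with age stays open, since age was not separated from the libraries.

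The 720 genes called between old and young uninjured fibroblasts kept a median of 0.924 of their log2 change within single clusters. This argues against a different mix of clusters for these genes as a set, though not for the alveolar and adventitial identity lists (medians given above). A difference of whole libraries that every cell class shares stays open. The cells outside the 3 tested classes, with a median of 0.851 times the fibroblast change (bound 0.75), cannot decide this, as their mix differs. Dendritic cells were 83 of 160 and 27 of 50 in young uninjured libraries, and 76 of 391 and 34 of 251 in old ones. Within classes, Zfp185 stood at 227 and 233 CPM in young uninjured fibroblasts and 34.4 and 50.2 in old ones. In alveolar macrophages it was 196 and 147 against 21.3 and 36.2. Age could act on every class too, so age, library preparation and RNA shared between cells cannot be told apart with 2 libraries per group.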
